A study of Mus musculus with 6 samples.

How the data were processed

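RNA from aorta of 3 eNOS-deficient and 3 wild-type samples was measured, after biotin labelling of cDNA from 300 ng of total RNA per the labels' protocols, on 1 Affymetrix array per sample. The deposited series table holds log2 values, which per the submitters' processing notes came from RMA (background correction, quantile normalization and summary of the probes of a probe set) in Affymetrix Expression Console 1.3.1. Those values were used as deposited. Scanner and single-probe values were not used here, so background correction and probe summary were not repeated. Quantile normalization is meant to remove global differences in total signal between samples, although array medians of the deposited values still differed slightly. The labels state genotype, tissue and age matching; sex, strain, allele, time of collection and array batch are not given in the sources used here.

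Probe sets were named through the platform's annotation table. Of 41345 probe sets, 23525 listed exactly 1 gene symbol, 1810 listed several and 16010 listed none. Gene IDs of 23328 single-symbol probe sets were found in the RefSeq gene table, and 0 symbols changed. No build is named by the files, so that table served only for names, chromosomes and which genes neighbour each other. For each of 22184 genes the probe set with the highest mean over the 6 arrays was kept (1082 genes had over 1), and genes whose mean lay under the 25th percentile of all probe sets, 4.38 log2, were left out, which left 18008. Probe sets with several genes or no gene were tested separately and are not named.

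The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, no covariates) and Benjamini-Hochberg adjustment over 18008 genes at 0.05, with a fold of at least 1.5 as a second requirement for naming. Single values and array means were compared by exact permutation, which with 3 against 3 gives 10 splits and no p under 0.1. Gene lists written before the data were examined, 34 in all with 845 symbols of which 743 were measured (6 through a synonym), were tested with camera at a preset correlation of 0.01 where at least 3 members were measured, which left 33, adjusted over the lists, with an estimated correlation and fry as alternatives. Lists of squamous epithelium, Y-linked, clock phase and germinal centre genes were written after the arrays had been looked at and were used for checks only.

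Genes named in the text followed a rule fixed before the data were examined. It took Nos3, then the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a fold of at least 1.5 and no overlap between groups, with places left over filled by the smallest unadjusted p without overlap, and up to 4 members of each list by smallest p. Predicted and uncharacterised genes, microRNAs, small nucleolar RNAs, chemosensory receptors and pseudogenes were passed over. Other genes, such as keratins and markers of single arrays, were chosen after their values were seen.

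Alternatives planned beforehand were no dim filter or a 50th percentile filter, an intensity trend with robust variance, the mean of a gene's probe sets, median centring, repeated quantile normalization, array weights, adipocyte markers as a covariate, another threshold, each array left out in turn, and windows of 5 and 20 Mb around Nos3 in place of 10 Mb. Alternatives added after seeing the data were covariates for Y-linked genes, epithelium and skeletal muscle, leaving out eNOS-deficient 11 and wild type 5 together, leaving out genes on X and Y, and an unadjusted threshold for the genes near Nos3. The scripts were tested on simulated data for 18008 genes with 3 arrays per group and the measured spread: changed genes were recovered in 2% of cases at a fold of 1.5, 58% at 2, 92% at 4 and 100% at 8, with 5 false calls, and a list shifted by 0.5 log2 was found at a median of 0.50, beside which 2 unshifted lists also passed. In that simulation every gene was drawn independently of the others. The estimated correlation within a list reached 0.956 in the data (lymphocyte genes), so the simulation cannot show how many unshifted lists pass there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.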

Results

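Aortas of mice lacking endothelial nitric oxide synthase (eNOS), the enzyme encoded by Nos3 that makes nitric oxide in the vessel lining, were set against aortas of wild-type mice of matched age. Total RNA from 3 eNOS-deficient samples (11, 15 and 19) and 3 wild-type samples (2, 3 and 5), named by the numbers in their titles, was hybridised to 1 Affymetrix array each. The log2 table held 41345 probe sets, and 18008 genes entered the tests. Array medians were 5.55, 5.58 and 5.59 on eNOS-deficient 11, 15 and 19. On wild type 2, 3 and 5 they were 5.63, 5.61 and 5.68, without overlap of the genotypes. Pearson's r between arrays lay between 0.947 and 0.983 across probe sets, which are not independent replicates. No pair of arrays shared over 0.109% of its values exactly, so no array was a copy of another. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.156. The labels do not say whether samples came from separate animals, so p-values measure only the spread between these samples.

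Nos3, the targeted gene, was reported first as a check of the labels. Its signal was 7.26 ± 0.13 log2 (SD, n = 3) in eNOS-deficient aorta and 7.74 ± 0.34 in wild type, a difference of -0.48 (standard error 0.19) that did not pass the test over all genes (limma adjusted p = 0.399). The eNOS-deficient arrays stood at 7.13, 7.39 and 7.27, and the wild-type arrays at 7.99, 7.88 and 7.36. Wild type 5 thus lay inside the eNOS-deficient range, and the two-sided exact permutation p was 0.2, where 3 samples against 3 cannot go below 0.1. Endothelial genes were low on that array too: 29 of them, without Nos3, averaged 8.03, 8.10 and 7.34 on wild type 2, 3 and 5 and 7.54 to 7.85 on the eNOS-deficient arrays. Relative to that mean, a comparison chosen after seeing the data, Nos3 differed by -0.38 log2 without overlap of the groups (exact permutation p = 0.1). The targeted allele and the position of the probes relative to the deleted part are not given in the sources used here, so this signal neither checks nor contradicts the labels of single arrays.

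Across the genome, 5 of 18008 genes passed an adjusted p under 0.05 in limma, 2 higher and 3 lower in eNOS-deficient aorta, all by a fold of at least 1.5. Fam205a2 was higher by 1.54 log2 (95% interval 1.23 to 1.85, adjusted p = 0.0344), at 6.93 ± 0.18 against 5.39 ± 0.055. Apol11b, of the apolipoprotein L family, fell by 2.36 (interval -2.89 to -1.83, adjusted p = 0.0419), from 6.76 ± 0.27 to 4.40 ± 0.38. The lower value is close to the dim filter level of 4.38, so the size of that fall is uncertain. The others are a microRNA and predicted genes outside the naming rule and were chosen after their values were seen. Gm3893 was higher by 2.45 (adjusted p = 0.0197), Mir301b fell by 2.02 (adjusted p = 0.0419) and Gm10923 was 2.47-fold lower (adjusted p = 0.0344). For all 5 the eNOS-deficient arrays lay wholly to 1 side of the wild-type arrays. Fam205a2 has 4 further probe sets with differences of 0.78 to 0.82. These come in pairs with the same difference and mean level, so they are not 4 separate measurements. Gm3893 has a pair with 2.16 and 2.59. Gm3893 and Fam205a2 are both placed on chromosome 4, Apol11b and Gm10923 both on chromosome 15, and Mir301b on chromosome 16. Where these probes lie along the chromosomes, and whether they also read other genes, was not tested. Leaving out eNOS-deficient 11, eNOS-deficient 19, wild type 2 or wild type 3 gave 0 genes, leaving out eNOS-deficient 15 gave 5 higher and 1 lower, and leaving out wild type 5 gave 2 higher and 0 lower. At an unadjusted p under 0.05 there were 1415 genes higher and 669 lower, where 900 in all would be expected if no gene differed. That split was 885 and 626 after repeated quantile normalization and 2028 and 388 with arrays centred on their medians. At 3517 genes (19.5%, chance 10%) the groups of arrays did not overlap.

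**Figure D1:**
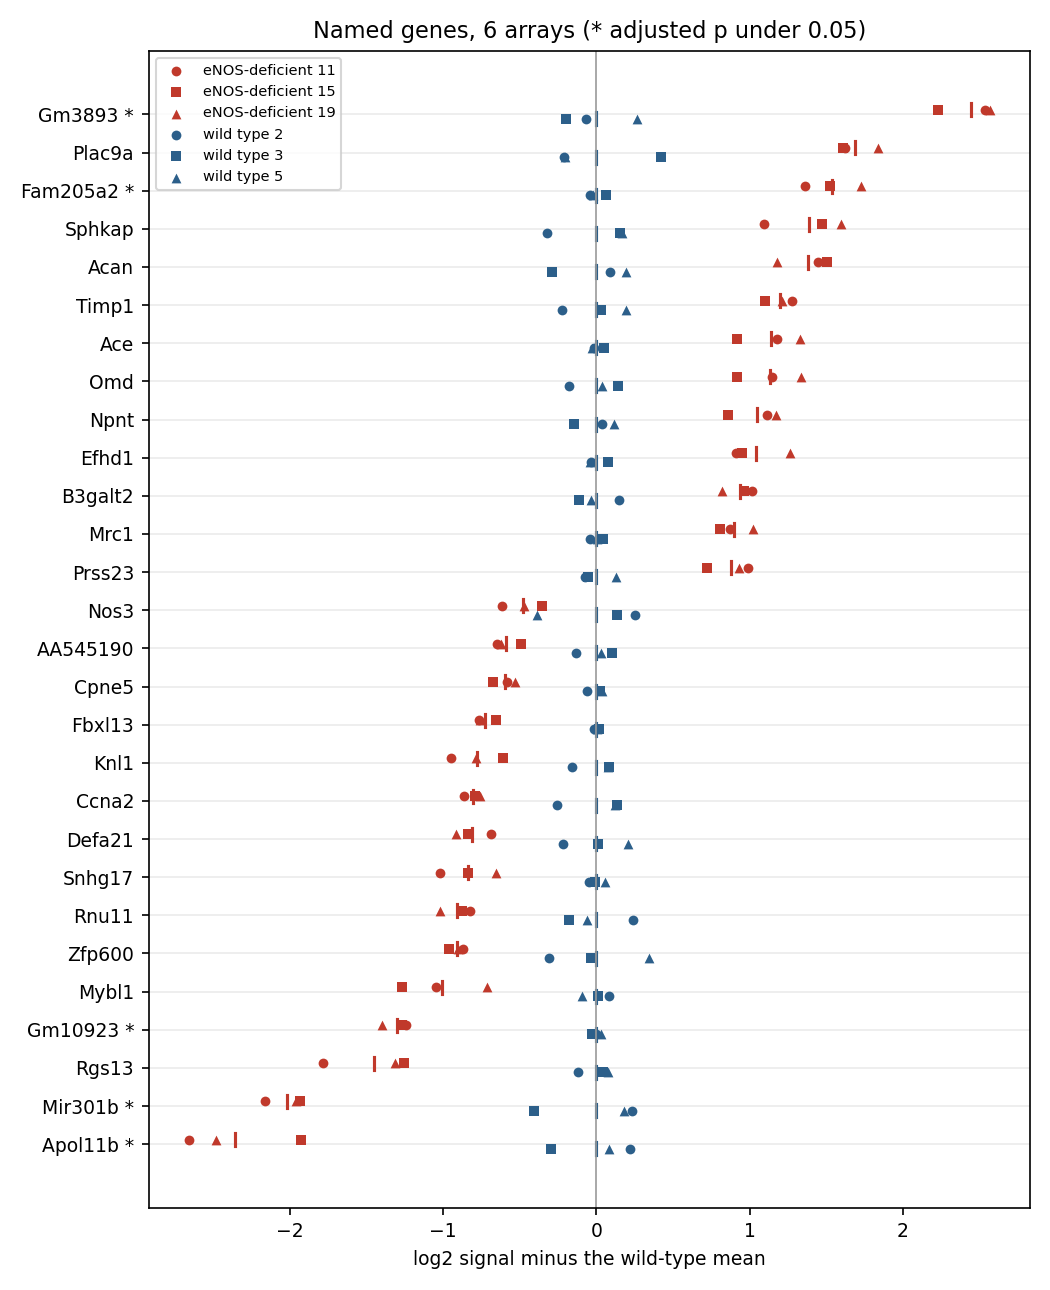
Log2 signal minus the wild-type mean (horizontal axis) of Nos3 and the other named genes (vertical axis) on each of 6 arrays; points are arrays, red for eNOS-deficient and blue for wild type, short bars are group means (each wild-type bar is at 0 by construction), and asterisks mark the 5 genes past the test. For Nos3 the wild type 5 point lies among the eNOS-deficient points, whereas for Gm3893 (2.45) and Apol11b (-2.36) the groups stand far apart.

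The remaining places of the naming rule were filled by smallest p, and none of these genes passed the test. On the higher side their limma adjusted p ran from 0.1 to 0.198, on the lower side from 0.1 to 0.216, and for each the groups of arrays did not overlap. Timp1, an inhibitor of matrix metalloproteinases, measured 6.81 ± 0.089 against 5.61 ± 0.21, and Acan, the cartilage proteoglycan aggrecan, 6.24 ± 0.17 against 4.86 ± 0.25. Omd, a small leucine-rich proteoglycan, differed by 1.13 log2, and Npnt, an extracellular integrin ligand, by 1.05. Ace, which converts angiotensin I to angiotensin II, measured 9.23 ± 0.21 against 8.08 ± 0.041. Mrc1, the macrophage mannose receptor, differed by 0.90 log2 (standard error 0.12). Plac9a differed by 1.69, Sphkap by 1.39 and B3galt2 by 0.94. Both other probe sets of Plac9a gave 1.73 at the same mean level, so they are not separate measurements. For Efhd1 (1.04) and Prss23 (0.88) a second, dimmer probe set gave 0.14 and 0.20.

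On the lower side, Rgs13, a regulator of G-protein signalling, measured 4.06 ± 0.29 in eNOS-deficient aorta against 5.51 ± 0.11. Mybl1, a transcription factor of the Myb family, differed by -1.01. Ccna2, encoding cyclin A2, measured 5.80 ± 0.053 against 6.61 ± 0.22, and Knl1, a kinetochore gene, differed by -0.78. The U11 small nuclear RNA gene Rnu11 differed by -0.91, Zfp600 by -0.91, the alpha-defensin gene Defa21 by -0.81, Fbxl13 by -0.73, Cpne5 by -0.60 and AA545190 by -0.59. Snhg17, a small nucleolar RNA host gene, gave -0.84 on its brightest probe set and -0.20 and -0.64 on the others.

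Of 33 gene lists fixed before the data were examined, 14 were higher and 2 lower in eNOS-deficient aorta by camera with a preset correlation of 0.01. No list passed when the correlation was estimated (0 higher, 0 lower), and fry, which does not compare a list with other genes, passed 3: extracellular matrix, osteochondrogenic and oxidative stress (adjusted p = 0.0288 for each). Other splits of the 6 arrays into 3 and 3 passed 6 to 15 lists, and 10 splits are too few for a share under 0.05. Averaged per array, 13 of the 33 lists had groups that did not overlap, 12 higher and 1 lower, where chance gives 10%. No list member passed over all genes, and the counts of members below are adjusted over the list alone.

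Extracellular matrix genes gave the clearest list. Of 44 measured, 43 had a positive difference and 21 rose, none fell and 23 did not pass (median 0.48, camera adjusted p = 4.11e-15, adjusted p = 0.258 with an estimated correlation). The list mean was 8.33 ± 0.028 on the eNOS-deficient arrays and 7.82 ± 0.11 on the wild-type arrays. Fn1 (fibronectin) rose by 0.94 log2 (standard error 0.14), Eln (elastin) by 1.05 (0.19) and Bgn (biglycan) by 0.74 (0.13). The crosslinking enzymes Lox and Loxl1 rose by 0.82 and 0.66, the matrix-degrading enzymes Mmp3 and Mmp9 by 1.37 and 0.77, and their inhibitors Timp1 and Timp2 by 1.20 and 0.71. Ccn2, a target of transforming growth factor beta, rose by 1.09, and Tgfb2 and Tgfb3 by 0.63 and 0.59. Adventitial fibroblast and mesothelial markers, 3 of which are also in the matrix list, rose for 7 of 21 members (median 0.46, camera adjusted p = 6.44e-05, adjusted p = 0.470 with an estimated correlation), among them the fibroblast markers Pi16 by 1.26 and Pdgfra by 0.60. Without wild type 2 the fibroblast median was 0.31 and still past, and the fibroblast list mean lay 0.27 above the wild-type mean on wild type 5, against 0.31 to 0.46 on the eNOS-deficient arrays. On the same arrays, 33 squamous epithelium genes averaged 5.25 ± 0.023 in eNOS-deficient and 6.67 ± 1.65 in wild-type aorta, with 8.55 on wild type 5 against 6.01 and 5.44 on wild type 2 and 3, and 3 Y-linked genes 6.82 ± 1.84 and 3.55 ± 0.084.

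Macrophage and monocyte genes rose for 11 of 27 members, and none fell (median 0.50, camera adjusted p = 2.43e-07, adjusted p = 0.383 with an estimated correlation). The macrophage list mean lay 0.14, 0.44 and 0.73 above the wild-type mean on eNOS-deficient 11, 15 and 19, and 0.14 above it on wild type 5. Lymphocyte genes, which did not pass, ranked the eNOS-deficient arrays in the same order (-1.72, 0.28 and 0.70). Csf1r, the receptor for colony-stimulating factor 1, rose by 0.98 (standard error 0.16), the complement C1q genes C1qb and C1qc by 1.11 and 0.94, and Folr2 and Mrc1, of resident tissue macrophages, by 1.16 and 0.90. Of 13 complement genes, 2 rose, the anaphylatoxin receptors C5ar1 (0.73) and C3ar1 (0.69) that myeloid cells carry (median 0.32, or 0.23 to 0.58 over the alternatives, camera adjusted p = 0.00029, adjusted p = 0.327 with an estimated correlation). Lymphatic endothelial genes rose for 2 of 8, Lyve1 (1.05), which macrophages also express, and Thy1 (0.53), which fibroblasts also express (median 0.53, camera adjusted p = 0.001, adjusted p = 0.333 with an estimated correlation). Inflammatory cytokines and chemokines did not pass (27 genes, median 0.05, camera adjusted p = 0.176), although they passed as higher without eNOS-deficient 11 (0.18) or without wild type 5 (0.15). The differences of -1.42 log2 in squamous epithelium genes (-0.47 without wild type 5), and of 3.28 in Y-linked genes, lay between the same groups. Y-linked means lay 4.22, 1.16 and 4.46 above wild type on eNOS-deficient 11, 15 and 19, which is not the order of the macrophage list. The wild-type Y-linked mean, 3.55, lies under the dim filter level of 4.38, so the size of that difference is uncertain.

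Cell cycle genes fell for 13 of 30 members and rose for none (median -0.39, camera adjusted p = 3.24e-11, adjusted p = 0.327 with an estimated correlation). Mki67, the proliferation marker Ki-67, fell by 1.25 (standard error 0.26), Top2a, a topoisomerase of dividing cells, by 0.85 and Ccna2 by 0.81. Interferon response genes formed the other lower list, with 1 of 26 members past, Rsad2, an antiviral gene that fell by 0.70 (median -0.07, camera adjusted p = 0.0217, adjusted p = 0.767 with an estimated correlation). The array means of the interferon list ran from 6.43 to 6.88 in eNOS-deficient aorta and overlapped wild type, and its median was 0.066 without eNOS-deficient 11 and -0.081 without wild type 5, neither past, and -0.17 and past without eNOS-deficient 19. For the cell cycle list, eNOS-deficient 11 lay lowest (-0.55 from the wild-type mean, against -0.33 and -0.18 on 15 and 19), as it did for lymphocyte genes (-1.72), and without it the median was -0.30 and still past. Wild type 2 lay at -0.16, close to eNOS-deficient 19. Squamous epithelium genes (-1.42, or -0.47 without wild type 5) and Y-linked genes (3.28) differed between the same groups.

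Among lists tied to vessel tone, the nitric oxide and cyclic GMP pathway did not pass (37 genes, median 0.12, camera adjusted p = 0.109). Its median was 0.14 and past without wild type 2. It was 0.038 without wild type 5 and -0.00092 with epithelium markers as a covariate, neither past. Of its members 1 rose: Kcnmb1, a subunit of the calcium-activated potassium channel of smooth muscle, by 0.75 (standard error 0.13). Vasoactive peptides, prostanoids and their receptors were higher as a list (32 genes, median 0.24, camera adjusted p = 0.0103, adjusted p = 0.306 with an estimated correlation), with Ace (1.14) and the serotonin receptor Htr2a (0.72) past and 30 not. Without wild type 5 the vasoactive list no longer passed (median 0.14). Contractile smooth muscle genes had 1 of 26 past, Cnn1 (calponin, 0.77), with Acta2 at 12.65 ± 0.13 against 12.37 ± 0.056 and not past (median 0.29, camera adjusted p = 0.00286, adjusted p = 0.473 with an estimated correlation). In this list 22 differences were positive and 4 negative, and the smooth muscle gene Myh11 differed by -0.27. With Y-linked genes as a covariate, chosen after seeing the data, the direction of that list's test turned, while its median stayed positive at 0.057. Smooth muscle phenotype switching had Fn1 and Tnfrsf11b past of 17 (median 0.23, camera adjusted p = 0.0225, adjusted p = 0.306 with an estimated correlation), and did not pass without eNOS-deficient 19 (0.094) or without wild type 3 (0.25). Osteochondrogenic and calcification genes had 5 of 19 higher, led by Acan (1.38), Comp (1.17) and Tnfrsf11b (1.10), which encodes the calcification inhibitor osteoprotegerin, and 1 lower, Snorc, which fell by 0.47 (median 0.20, or 0.12 and still past without wild type 5, camera adjusted p = 0.0148, adjusted p = 0.306 with an estimated correlation). The differences in squamous epithelium genes (-1.42, or -0.47 without wild type 5) and Y-linked genes (3.28) lay between the same groups here too.

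Coagulation and fibrinolysis genes had 4 of 21 higher and none lower (median 0.19, camera adjusted p = 0.00416, adjusted p = 0.306 with an estimated correlation): F13a1 (1.00), which macrophages express, Serping1 (0.98), Serpinf1 (0.80) and Plat, tissue plasminogen activator (0.58). Without eNOS-deficient 19 the coagulation median was 0.11 and still past. Oxidative stress and antioxidant genes had 0 of 32 past in limma, with 6 at an unadjusted p under 0.05 (median 0.17, camera adjusted p = 0.0148, adjusted p = 0.306 with an estimated correlation); the glutathione peroxidase Gpx3 measured 8.88 ± 0.27 against 8.10 ± 0.35. After repeated quantile normalization the oxidative stress list had a median of 0.036 and did not pass. Heat shock and unfolded protein genes likewise had 0 of 26 past in limma, with 3 at an unadjusted p under 0.05 (median 0.14, camera adjusted p = 0.0348, adjusted p = 0.767 with an estimated correlation), and did not pass without eNOS-deficient 19 (0.042), wild type 2 (0.097) or wild type 3 (0.19). With Y-linked genes as a covariate, chosen after seeing the data, heat shock genes turned to a median of -0.085. Brown adipocyte genes had 1 of 16 past, the deiodinase Dio2, by 0.67 (median 0.20, camera adjusted p = 0.0225, adjusted p = 0.510 with an estimated correlation), and Ucp1, the brown fat uncoupling protein, stood at 12.91 to 13.12 on all 6 arrays. The brown adipocyte list did not pass without eNOS-deficient 15 (0.085) or without wild type 5 (0.11). Skeletal muscle genes had 0 of 20 past in limma and 0 at an unadjusted p under 0.05, with all 20 positive and with groups of arrays that overlapped (median 0.59, camera adjusted p = 0.0189, adjusted p = 0.844 with an estimated correlation). The skeletal muscle list mean lay 1.64 above wild type on eNOS-deficient 11 and 0.17 and 0.082 above it on 15 and 19. The list did not pass without eNOS-deficient 11 (0.16, camera adjusted p = 0.945), wild type 3 (0.17, 0.859) or wild type 2 (0.52, 0.0861), and its median was 1.11 and past without wild type 5. With Y-linked genes or with its own markers as a covariate its median was near 0 (0.0029 and -0.00091) and the test turned. For all lists of this paragraph the groups also differed in squamous epithelium genes (-1.42, or -0.47 without wild type 5) and Y-linked genes (3.28).

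**Figure D2:**
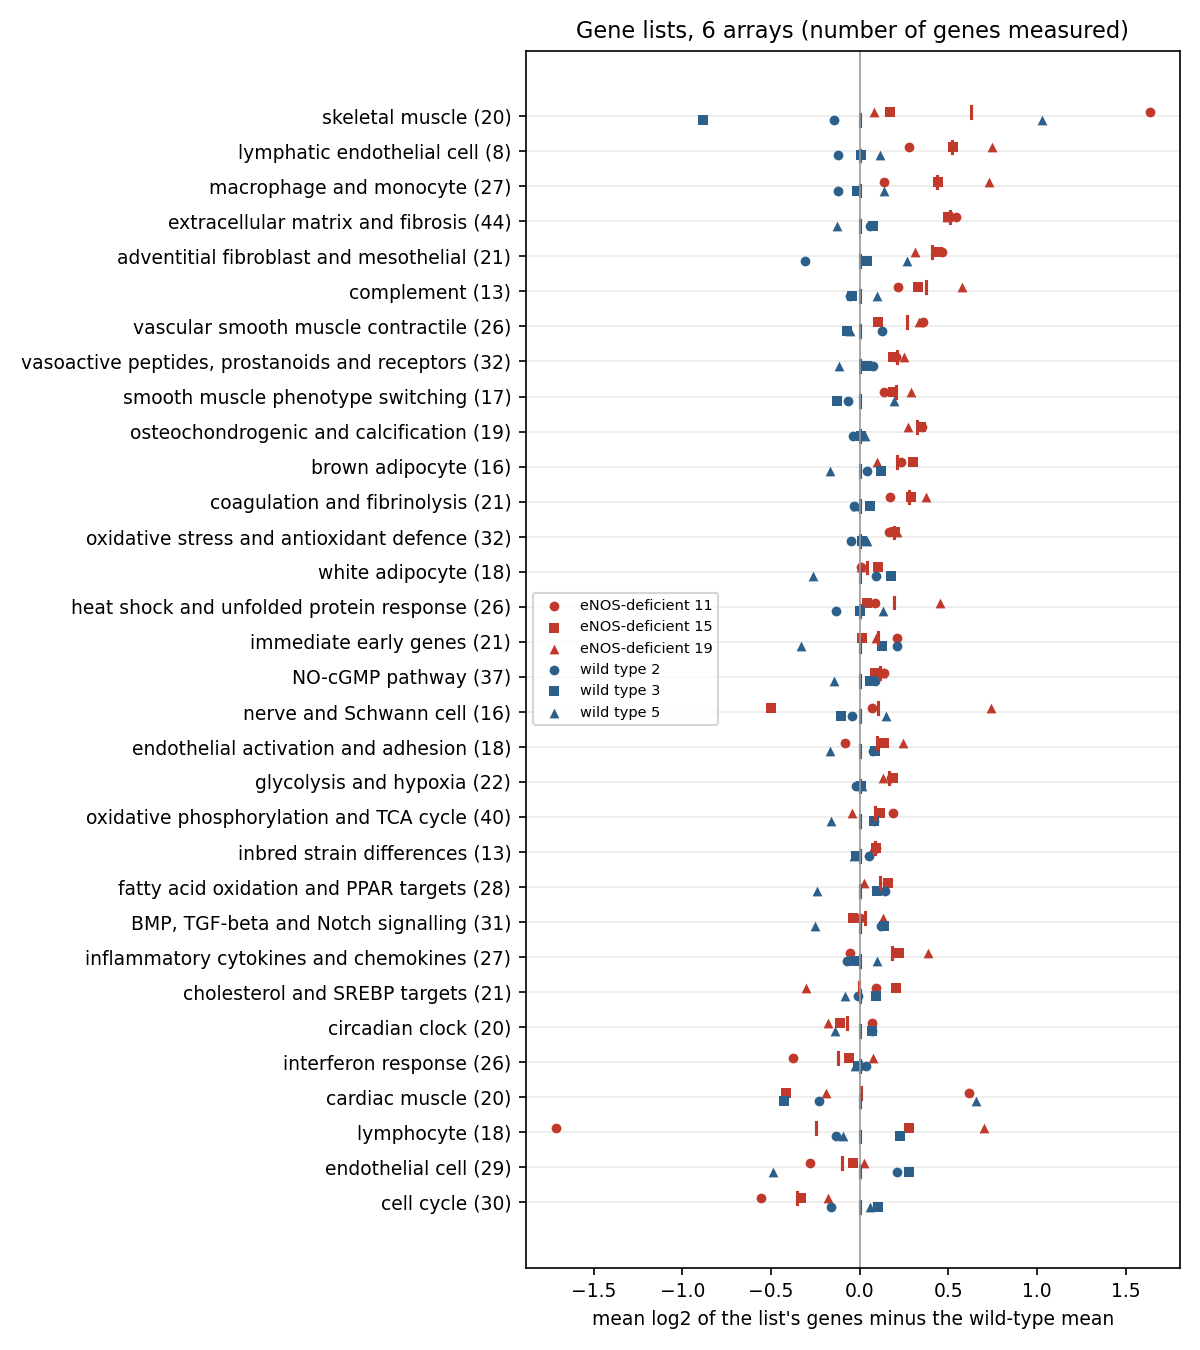
Mean log2 signal of each gene list minus the wild-type mean (horizontal axis, log2) on each of 6 arrays, for 32 of the 33 lists tested (vertical axis, genes measured in parentheses; the 4 sex-linked genes are left out); points are arrays, red for eNOS-deficient and blue for wild type, and short bars are group means. Matrix genes separate the groups with little spread (8.33 ± 0.028 against 7.82 ± 0.11), whereas eNOS-deficient 11 is the highest array for skeletal muscle genes and the lowest for lymphocyte genes.

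The other lists did not pass camera with all 6 arrays. Endothelial cell genes had a median of -0.18 over 29 genes (camera adjusted p = 0.130) and endothelial activation and adhesion genes one of 0.09 (0.461). The endothelial list mean lay 0.49 below the wild-type mean on wild type 5 and 0.21 and 0.28 above it on wild type 2 and 3. Without wild type 5 the endothelial list passed as lower (median -0.41, camera adjusted p = 2.39e-07), as it did without eNOS-deficient 19 (-0.18, 0.0387), and its median was -0.021 without wild type 2. Cdh5, the endothelial cadherin, ran from 10.06 to 10.40 on the eNOS-deficient arrays and stood at 11.02, 10.66 and 9.75 on wild type 2, 3 and 5. Of the 29 endothelial genes 18 were lower and 11 higher, and the 1 at an unadjusted p under 0.05 in limma was higher. Emcn differed by 0.28 (9.92 to 10.01 against 9.58 to 9.78 in wild type) and Egfl7 by -0.58. Ecscr and Erg were higher in every alternative (0.13 to 0.39 and 0.0073 to 0.59). The median was -0.13 for lymphocyte genes (camera adjusted p = 0.145), 0.15 for white adipocyte genes (0.570), -0.09 for cardiac muscle genes (0.462), 0.11 for nerve and Schwann cell genes (0.887), 0.12 for immediate early genes (0.502) and 0.06 for signalling by BMP, TGF-beta and Notch (0.949). Metabolic lists had medians of 0.08 for oxidative phosphorylation (camera adjusted p = 0.145), 0.06 for fatty acid oxidation (0.173), 0.08 for glycolysis and hypoxia (0.187) and -0.01 for cholesterol synthesis (0.623). Without wild type 5 the median was -0.011 for white adipocyte, -0.022 for immediate early and 0.0079 for glycolysis and hypoxia genes, none past. For endothelial activation it was -0.022 without eNOS-deficient 19, also not past. Lymphocyte genes passed as higher without eNOS-deficient 11 (0.43) and as lower without 15 (-0.32) or 19 (-0.55). Nerve genes passed as higher without eNOS-deficient 15 (0.38) and as lower without 19 (-0.19), and cardiac muscle genes as lower without 11 (-0.19). Oxidative phosphorylation and fatty acid oxidation passed as higher without eNOS-deficient 19 (0.15 and 0.11) or without wild type 2 (0.12 and 0.14). Without wild type 5 their medians were -0.018 and 0.010, neither past. For cardiac muscle the list mean was positive (0.005) while the median and the direction of the test were negative. Of the erythroid list 2 genes were measured, too few for a list test, Slc4a1 with -0.38 and Epb42 with -0.41, neither past.

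Circadian clock genes moved in opposite directions and did not pass as a list (20 genes, median -0.07, camera adjusted p = 0.208), although the list passed as lower in 4 of 18 alternatives, among them without eNOS-deficient 11 (-0.17). Npas2 and Arntl (Bmal1), activators of the clock, rose by 1.65 (standard error 0.26) and 1.21 (0.26), whereas Dbp, Per3 and Ciart, which the clock drives in the opposite phase, fell by 1.06, 1.06 and 0.69. The other 15 members did not pass. None of the 5 passed over all genes (limma adjusted p = 0.198 to 0.289). Over 19 alternatives Npas2 passed in 5, Arntl and Ciart in 1 each and Dbp in 0. The array labels state no time of collection. Squamous epithelium genes (-1.42, or -0.47 without wild type 5) and Y-linked genes (3.28) differed between these groups as well.

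**Figure D3:**
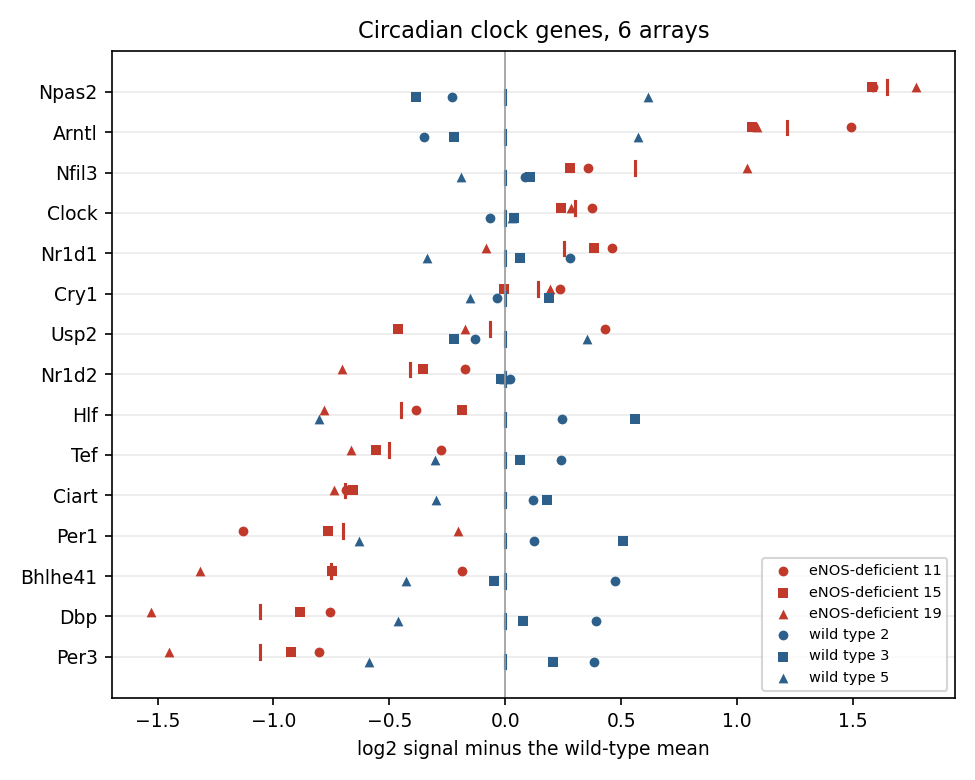
Log2 signal minus the wild-type mean (horizontal axis) of 15 clock genes (vertical axis, ordered by difference) on each of 6 arrays; points are arrays, red for eNOS-deficient and blue for wild type, and short bars are group means. Npas2 (1.65) and Arntl (1.21) lie to the right and Dbp (-1.06) and Per3 (-1.06) to the left, with wild type 5 nearest to the eNOS-deficient arrays for these 4 genes.

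Sex-linked genes and markers of other tissues set arrays apart within and between the genotypes. Xist, the RNA of the inactive X chromosome, stood at 12.08 to 12.09 on the 3 wild-type arrays and at 5.65, 11.88 and 8.29 on eNOS-deficient 11, 15 and 19. The Y-linked gene Eif2s3y stood at 8.08, 4.70 and 8.51 on those eNOS-deficient arrays and between 2.86 and 3.44 in wild type. All 4 measured sex-linked genes passed adjusted over the list alone (Eif2s3y, Kdm5d and Uty higher, Xist lower), and as a list they did not (median 2.96, camera adjusted p = 0.0509), although the list passed in 4 of 16 alternatives, among them without eNOS-deficient 15 (3.95). The labels give no sex, and with Y-linked genes as a covariate no gene passed in limma (276 higher and 227 lower at an unadjusted p under 0.05). With that covariate Gm3893 went from 2.45 (standard error 0.17) to 2.13 (0.30), Fam205a2 from 1.54 (0.13) to 1.502 (0.28), Apol11b from -2.36 (0.22) to -1.72 (0.33), Mir301b from -2.02 (0.19) to -1.90 (0.38) and Gm10923 to -1.25 (standard error 0.11 before and 0.23 after). The calls ended mainly because the standard errors grew, and the differences moved least for Fam205a2 and most for Apol11b. The Y-linked mean lay 4.22, 1.16 and 4.46 above wild type on eNOS-deficient 11, 15 and 19. Its SD in wild type was 0.084. The covariate thus largely follows the genotype, and the adjusted differences rest mainly on eNOS-deficient 15, which may hold RNA of both sexes. The differences kept with it therefore do not show that these 5 genes are independent of sex. Squamous epithelium transcripts were high on wild type 5, where the keratins Krt4 and Krt13 reached 13.33 and 12.18, and present on wild type 2 (9.64 and 7.90) and lower on wild type 3 (6.18 and 5.64), against 4.41 to 5.16 and 4.64 to 5.25 on the eNOS-deficient arrays, so both keratins separated the genotypes. Skeletal muscle Myh4 was highest on eNOS-deficient 11 (11.72) and lowest on wild type 3 (7.46), and the B-cell gene Ms4a1 was lowest on eNOS-deficient 11 (5.24, against 7.95 to 8.65 elsewhere). Among lung and airway genes, Sftpc stood at 9.92 on eNOS-deficient 19 and 6.46 on wild type 5, against 4.75 to 5.03 on the others. Scgb1a1 stood at 8.99, 5.24 and 4.37 on wild type 2, 3 and 5, against 3.34 to 3.49 in eNOS-deficient aorta. Without both eNOS-deficient 11 and wild type 5, chosen after seeing the data, 2 genes were higher and 0 lower, and 14 lists were higher and 3 lower.

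**Figure D4:**
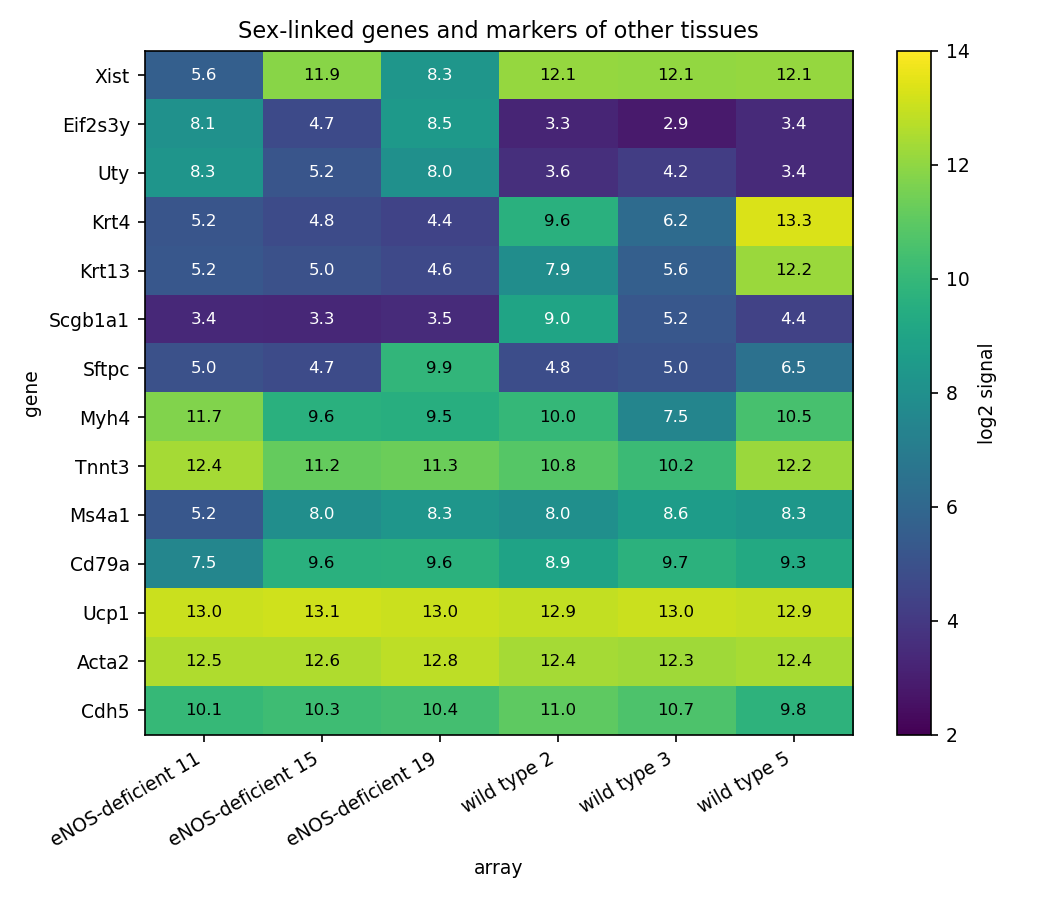
Log2 signal (colour scale and printed values) of sex-linked genes and of markers of squamous epithelium, lung and airway, skeletal muscle, B cells, brown fat, smooth muscle and endothelium (rows) on the 6 arrays (columns). Xist reaches 12.08 to 12.09 on the wild-type arrays and 5.65 on eNOS-deficient 11, Krt4 peaks on wild type 5 (13.33), and Ucp1 stays between 12.91 and 13.12.

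Genes near Nos3 on its chromosome were examined because DNA of the stem-cell donor strain can stay beside a targeted gene. None of 160 tested genes within 10 Mb passed in limma, against 5 of 17711 elsewhere (Fisher's exact p = 1, two-sided). With only 5 genes past the test, a count of 0 there was likely in any case and decides little. At an unadjusted p under 0.01, a threshold added after seeing the data, 4 genes (2.5%) near Nos3 and 590 (3.33%) elsewhere were counted (Fisher's exact p = 0.823). In other windows the share near Nos3 was above that elsewhere: 4 of 71 genes (5.63%, against 3.31%) within 5 Mb (Fisher's exact p = 0.301) and 10 of 252 (3.97%, against 3.31%) within 20 Mb (Fisher's exact p = 0.482). Camera on the genes near Nos3 gave an unadjusted p of 0.325 within 10 Mb, 0.0613 within 5 Mb and 0.515 within 20 Mb, each toward lower. Fbxl13, named above on the lower side and not past the test, lies within 10 Mb of Nos3. Its eNOS-deficient mean, 4.41, is close to the dim filter level of 4.38, so the size of its fall is uncertain. The inbred strain list, of genes known to differ between laboratory strains, had 0 of 13 genes past in limma, with 1 at an unadjusted p under 0.05 (median 0.07, camera adjusted p = 0.730).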

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

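The tests of explanations in this part and their bounds were chosen after the results were seen, although a covariate for adipocyte markers had been chosen before the data were examined. Among 11977 probe sets that list several genes or no gene, which the comparison of genes leaves out, 15 passed an adjusted p under 0.05 in limma, 13 higher and 2 lower in eNOS-deficient aorta. A signal outside the main measurement singled out this result. Of the 15, 8 list several genes and cannot be assigned to 1 of them, and 7 list no gene. Of the 13 higher, 6 list Gm3893 among their genes, so the 13 are not separate genes.

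The first pattern weighed was the rise of the matrix, fibroblast and macrophage lists, whose mean shift was 0.45 log2 (95% interval 0.24 to 0.66). Squamous epithelium in wild-type samples was tested as the whole of it. With epithelium markers as a covariate or without wild type 5, the lowest of the 3 list medians kept 0.962 of its value. The shift with the covariate was 0.51 (interval 0.21 to 0.80), and of the 33 epithelium genes 0 are in another list. The epithelium covariate was 8.55 on wild type 5, against 6.01 and 5.44 on wild type 2 and 3, so both checks bear mainly on wild type 5. They argue against epithelium on that array as the whole of the shift. Without it epithelium genes still differed by -0.47, so epithelium in wild type 2 and 3 stays open. Less perivascular fat in eNOS-deficient samples as the whole of it was tested with a covariate too: with adipocyte markers, the shift was 0.4876 (interval 0.22 to 0.75) and the 3 lists stayed past camera. That covariate is the mean of the brown and white adipocyte genes, so the fall of the brown adipocyte median from 0.20 to 0.066 came by construction. Both covariate tests used a lower 95% limit above 0, a bound set after these values were seen, so meeting it decides nothing. The limits, 0.221 for fat and 0.211 for epithelium, fall short of 50% of the shift (0.226), so a part played by either stays open. A first test of fat, the shift of the brown adipocyte list itself, did not settle it (0.209, interval -0.082 to 0.50), so less fat stays open. The means of the brown list and of the white list (0.039) were higher rather than lower in eNOS-deficient aorta, with groups that overlapped. Sex of the animals was not settled: the shift with the Y-linked covariate was 0.467 with an interval of -0.036 to 0.97, and Y-linked genes differed between the genotypes. On eNOS-deficient 15 Xist was 86.4% of the wild-type mean, and the Y-linked mean lay 1.16 above wild type, against 4.22 and 4.46 on 11 and 19. The matrix, fibroblast and macrophage means there lay 0.50, 0.44 and 0.44 above wild type. They lay 0.54, 0.46 and 0.14 above it on 11 and 0.49, 0.31 and 0.73 on 19. That is 1 array, which may hold RNA of both sexes, so sex stays open. The genotype itself stays open, and 16 lists passed in the real grouping against 15 in the highest of the other splits; 1 of 10 splits, the real one, reached 16, and 10 splits are too few for a share under 0.05.

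The second pattern was the clock genes of opposite phase. The mean of 5 genes of the Bmal1 phase minus that of 10 genes of the Dbp and Per phase was higher in eNOS-deficient aorta by 1.316 log2. All 15 belong to the circadian list and include the 5 genes that drew attention to it, so this value restates the observation. Without those 5 the difference was 0.7093, with the other 3 genes of the Bmal1 phase shifted by 0.33 (interval 0.014 to 0.65) and the other 7 by -0.38 (interval -0.90 to 0.15). Collection at different times of day and an effect of genotype on the clock cannot be told apart, since both predict opposite shifts and no time of collection is given. Sex of the animals was not tested for this pattern. The tables argue against epithelium in wild type 5 as the source, since without that array the difference was 1.579 rather than smaller.

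The third pattern was the 5 genes past the test, against 0 in the highest of the other splits (1 of 10 splits reached 5, and 10 splits are too few for a share under 0.05). Donor DNA beside Nos3, on chromosome 5, as their common source is argued against. All 5 are placed on other chromosomes (4, 15 and 16), and 0 lie within 10 Mb of Nos3. A strain difference elsewhere in the genome cannot be told apart from genotype, since 0 of 13 genes in the strain list passed and few strains differ in all of them. Signal shared by near-identical copies cannot be settled for Gm3893, as 6 of the 13 probe sets that list it with other genes were higher past the test.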

How the results depend on the processing

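The gene counts rest on few arrays, and the list counts rest on the preset correlation; dim genes were left out by level only, with no detection calls. No paired analysis was possible because the groups share no replicate number. Alternatives for covariates of Y-linked genes, epithelium and muscle, the pair of arrays left out and X and Y genes were chosen after seeing the data, and apart from fewer samples, fewer genes or another threshold where these apply, the cause was not tested. Against 2 genes higher and 3 lower, there were 2 and 1 without the dim filter, 1 higher and 1 lower with the mean of a gene's probe sets, 2 and 0 after repeated quantile normalization, 94 higher and 25 lower with array weights, 2 and 0 with adipocyte markers, 0 and 0 with Y-linked genes, 2 and 0 with epithelium markers, 1 higher and 0 lower with muscle markers, 2 and 0 without both eNOS-deficient 11 and wild type 5, and 249 and 87 at an unadjusted p under 0.01. Leaving out 1 array gave 0 to 5 higher and 0 to 1 lower. Against 14 lists higher and 2 lower, there were 17 and 1 without the dim filter, 9 and 5 with the 50th percentile filter, 12 and 4 after repeated quantile normalization, 10 and 3 with Y-linked genes (9 and 1 of them among the 14 and 2), 11 and 2 with muscle markers, 14 and 3 with epithelium markers, 0 and 0 with an estimated correlation, 3 and 0 with fry, and 11 to 15 higher and 2 to 5 lower with 1 array left out. Nos3 kept its direction in every alternative run and never passed, at -0.32 with Y-linked genes to -0.76 with epithelium markers, and 0 genes near it passed in windows of 5 and 20 Mb. With Y-linked genes as a covariate, medians became -0.085 for heat shock, 0.057 for contractile smooth muscle (the test's direction turned, the median did not) and 0.0029 for skeletal muscle, and skeletal muscle gave -0.00091 with its own markers. Single genes not past the test turned sign: with Y-linked genes Bag3 -0.098, Chac1 -0.18, Insig1 0.074, Cd79b 0.36, Uchl1 -1.06, Gfra3 -0.12, Kdm5d -0.59 and Xist 1.40; Csrp3 0.38 with epithelium markers; Cd79b 0.33 without both arrays; and Uchl1 -0.057 with array weights. With 1 array left out, Ighm ran from -1.86 to 0.18 and Cd79b from -1.05 to 0.20, both highest without eNOS-deficient 11, and Uchl1 from -0.073, without eNOS-deficient 19, to 0.88. Kdm5d is 1 of the 3 genes in the Y-linked covariate, which takes up its difference by construction; Xist is not in it. Repeated quantile normalization took medians to 0.036 for oxidative stress, 0.042 for brown adipocyte, 0.014 for heat shock and 0.092 for phenotype switching, none past. Of the lists not past, endothelial genes passed as lower in 7 of 18 alternatives, cytokines as higher in 6, and lymphocyte genes as higher in 2 and lower in 4; strain, white adipocyte, glycolysis, immediate early and endothelial activation genes passed in 0. The matrix list stayed past the test in 18 of 19 alternatives, the macrophage, cell cycle, fibroblast, complement, lymphatic, coagulation and osteochondrogenic lists in 17 each, contractile and oxidative stress in 16, vasoactive in 13, phenotype switching in 11, heat shock, brown adipocyte and skeletal muscle in 10 and interferon in 9, with interferon medians from -0.17 to 0.066 and skeletal muscle medians up to 1.40.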

Other observations

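The tests in this part were chosen after the arrays had been looked at, although the bound for the germinal centre list was written before its result was seen. Several list members not yet described differed between the groups without overlap and without passing over all genes. The leptin gene Lep measured 7.89 ± 0.12 log2 in eNOS-deficient aorta and 8.92 ± 0.71 in wild type, while Adipoq, encoding adiponectin, measured 8.70 ± 0.12 against 8.28 ± 0.12. Id2, a target of BMP signalling, measured 9.75 ± 0.14 against 9.04 ± 0.24, and Arg1, encoding the arginase that uses the substrate of eNOS, 5.22 ± 0.25 against 5.87 ± 0.34 (limma adjusted p = 0.236 and 0.334). The glutathione transferase Gsta3 measured 7.19 ± 0.30 against 6.20 ± 0.43, and the interferon-induced gene Iigp1 7.02 ± 0.35 against 7.78 ± 0.32.

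A hypothesis of germinal centre B cells in the wild-type samples was raised by Rgs13, Mybl1 and the cell cycle list, all lower in eNOS-deficient aorta. The 7 measured genes of a germinal centre list had a median difference of -0.1448 log2, with 5 lower, between the bounds set for and against it, so it stays open. The list mean was 6.72 ± 0.029 in eNOS-deficient and 6.84 ± 0.0069 in wild-type aorta, a small difference without overlap (exact permutation p = 0.1). Basp1 differed by -0.37 and Gcsam by -0.64, while Bcl6, which other cells also express, differed by 0.55; 0 of the 7 genes are in another list.

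Sex-linked genes on eNOS-deficient 15 and 19 may come from RNA of both sexes in 1 sample. On eNOS-deficient 19, where Y-linked genes were high, Xist reached 7.215% of the wild-type mean on the linear scale, against 1.15% on eNOS-deficient 11. On eNOS-deficient 15 Xist reached 86.4%, and all 3 measured Y-linked genes were above the highest wild-type array. Pooled animals, carry-over between samples and loss of a sex chromosome in some cells were not told apart.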
